A study of Mus musculus with 112 samples.

How the data were processed

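Total RNA in 112 samples of mouse ES cells was measured on 2-colour Agilent arrays, with the sample labelled in Cy3 and a common reference in Cy5. Per the labels' protocols the reference mixed RNA pooled from 11 mouse cell lines with ES cell RNA at 2 to 1. Cells carried an inducible factor that is expressed when Dox is absent, were plated on gelatin with Dox at 0.2 µg/ml, and were washed repeatedly about 18 h after plating into medium with or without Dox. Harvest followed 24, 48 or 72 h after the last wash, or, for the 0 h groups, without washing. Per the submitters' processing notes the images were read with Agilent Feature Extraction; its version, the background correction and the normalization are not given in the sources used here.

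The values used were the deposited table of 25030 features by 112 arrays, without missing values. The base of its logarithm is not stated. The deposited values were taken as log10 of a signal rather than of a ratio to the reference, because array medians lay at 2.21 to 2.29, values ran from -1.96 to 6.08, and the middle 99% of values would span 36400-fold on base 10 but 95.7-fold on base e and 23.6-fold on base 2. The replicate CV of bright features would be 5.03%, 2.15% and 1.49% on these bases. Values were multiplied to log2. Fold changes, SEs and the 1.5-fold limit rest on this base; adjusted p-values do not, and each count at an adjusted p under 0.05 alone is larger, for example 13653 in the Cdx2 clone and 8158 in the Pou5f1 clone. Whether the signal is of the Cy3 channel alone, and how it was scaled between arrays, stays unknown. Arrays were not normalized further. Flags for spots near background were not used here, so the size of a rise from a dim signal is uncertain.

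Samples were grouped by clone, Dox state and time as the labels give them, 57 groups in all. A mean for each group was fitted to all 112 arrays together with limma 3.58.1 (R 4.3.3, lmFit and eBayes, 55 residual and 1.29 prior degrees of freedom), so the 2 groups of 1 array are assumed to vary like the others. Contrasts were Dox-free minus Dox-kept at each time, their mean over 3 times, the 72 h effect minus the 24 h effect, and Dox-kept 24 to 72 h minus 0 h. P-values were adjusted by Benjamini-Hochberg within each contrast, and a feature was called at an adjusted p under 0.05 and a change of at least 1.5-fold (0.585 on the log2 scale). Sharing between clones was set against 10000 random placements of each clone's calls, one-sided, and pairs of clones were compared by Pearson correlation and by Fisher's exact test of the overlap. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

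The fit was tested on simulated arrays with the real features' means and spreads, and with noise independent between features and arrays. False calls from slides, from positions or from features that move together were therefore not simulated. In the simulated mean-over-times comparison of Cdx2 on 25030 features, 200 features changed at each size; 33.0% of those changed 1.5-fold, 82.0% of those changed 2-fold and 99.5% of those changed 4-fold were called, with 7 false calls and 0 calls in the other 8 clones, which held no change. In the simulated 72 h comparison, with 1 Dox-free array, the shares were 23.0%, 61.0% and 87.5%.

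The comparisons, the tests and the alternatives were set before the data were examined. They had been written for genes: named genes by size of change, the induced factor's own transcript, and 25 gene lists for lineages, pathways and other cell types. The files used here do not pair features with genes, so tests ran per feature, the gene lists and the factors' own transcripts were not analysed, and the induction itself was not checked on these arrays. The rule for features kept the part that needs no name, the 8 largest rises and falls per clone with the same direction at all times. Alternatives were quantile normalization, removal of the dimmest 25% of features (6258 features), slide as a random block, the replicate number as a block, each clone's own arrays alone, and leaving out each array in turn. Random placement within classes of brightness, the share of each clone in changes of the other 8, and the correlations at each time were added after the data were seen.

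Of the 27 comparisons of Dox state, 21 lie on 1 slide, 2 share a slide in part and 4 share none, over 35 slides in all. No arrays held identical values, and replicate pairs correlated at 0.986 to 0.997.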

Results

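The series followed gene expression in mouse embryonic stem (ES) cells after single transcription factors were induced. All clones came from the same parent line, MC1 cells of the 129S6/SvEvTac strain, in which a doxycycline-controlled expression cassette had been placed in the ROSA26 locus and then exchanged for a vector that encodes a tagged factor. The vector's factor was off while doxycycline (Dox) was in the medium and on after it was washed out. Dox-free cells were therefore set against Dox-kept cells of the same clone and time. The cells' own genes for these factors were not under this control, so Dox-kept cells may express them. The 9 clones analysed carried Pou5f1 and Sox2, which belong to the core pluripotency network; Klf4 and Myc, which together with them can reprogram fibroblasts; T (Brachyury), a T-box factor of mesoderm; and Cdx2, Gata3, Esx1 and Ascl2, factors with known roles in trophoblast or placenta. The series title counts 10 factors, and the tenth is not analysed here.

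RNA was taken at 24, 48 and 72 h, and in the Pou5f1, Sox2 and T clones also at 0 h with Dox kept. The arrays fell into 57 groups, 55 of them with 2 arrays. The Dox-free 72 h groups of Cdx2 and Esx1 had 1 array each, and that of Cdx2 was hybridised with a pool of 3 numbered samples. Each array gave 25030 features. Array medians lay between 2.21 and 2.29 on the log10 scale, and replicate arrays correlated at 0.986 to 0.997 across features. The median SD between replicates was 0.31 on the log2 scale over all features and 0.07 over bright features on the same slide. The number of arrays limits the precision of every value. The labels give the arrays of a group different sample numbers and do not say what a number stands for, such as a separate culture, so p-values measure the spread between these samples.

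The files used here do not pair feature numbers with genes. Responses are therefore described by the number, direction, size, timing and sharing of features, and 4 feature numbers are printed.

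The first comparison asked how far each factor moved the transcriptome of ES cells, averaged over 24, 48 and 72 h. Each factor was carried by a single clone. Differences between factors, here and in the later comparisons, therefore cannot be told apart from differences between clones. Induction of Cdx2 changed the most features, 3295 that rose and 3078 that fell, which is 25.5% of all features. Esx1 followed with 3274 rises and 2701 falls, Klf4 with 2962 and 2295, and Gata3 with 2656 and 2419. Sox2 (1775 rises, 1999 falls) and Ascl2 (1617 rises, 1316 falls) were intermediate. T (988 rises, 895 falls), Myc (398 rises, 957 falls) and Pou5f1 (667 rises, 610 falls) changed the fewest. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 in limma and a change of at least 1.5-fold.

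Direction was near balance in 8 of the 9 clones, where rises made up 47.0% (Sox2) to 56.3% (Klf4) of the called features. The Myc clone differed, with rises at 29.4%. After quantile normalization its share was 37.1%, and the others ran from 48.2% (Sox2) to 54.7% (Ascl2). The size of the Myc imbalance thus depends on the scaling between arrays. Risen features had started from lower signals than fallen ones in most clones. The Dox-kept arrays are also part of the contrast, so a low value on them favours a call as risen. In the Klf4 clone the median Dox-kept signal was 1.96 log10 for risen and 2.64 for fallen features, and in the Cdx2 clone 2.28 and 2.73. The Myc clone was again the exception, with 2.18 for risen and 2.03 for fallen features. The dimmest 25% of features had a mean signal over all arrays under 1.02 log10. Of the risen features, 508 of 2656 in the Gata3 clone and 230 of 1617 in the Ascl2 clone started below this level. Of the fallen features, 0.8% (Esx1) to 4.9% (T) did.

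The sizes of single responses ranged widely. The largest rise in the Gata3 clone was 7.25 ± 0.24 (SE) on the log2 scale, or 152.5-fold (limma adjusted p = 1.26e-34), and the same feature already stood 5.46 higher at 24 h and reached 8.98 at 72 h. In the Cdx2 clone the largest rise was 6.57 ± 0.20, with 6.09 at 24 h, 7.54 at 48 h and 6.09 at 72 h, and that feature also rose by 6.45 in the Gata3 clone. The largest rises in the other clones were 5.46 for Klf4, 5.13 for Ascl2, 4.65 for Sox2, 4.56 for T, 4.54 for Esx1, 3.69 for Pou5f1 and 3.02 for Myc. Feature 5084 was the largest riser in both the Pou5f1 and the Myc clone. The deepest falls were -5.90 ± 0.05 in the Cdx2 clone, a feature that started at 4.68 log10, -5.22 in the Esx1 clone and -4.86 in the Klf4 clone.

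Most of the strongest responders were called the same way in another clone as well. Among the 8 largest falls per clone that kept their direction at all times, all 8 fell in at least 1 other clone in 8 of the 9 clones, and 7 of 8 did in the Pou5f1 clone. Of the 72 largest rises, 62 were called as rises in another clone and 10 in none. Opposite calls were common too: 37 of these 72 rises and 35 of the 72 largest falls were called the other way in some other clone. A feature that rose by 6.32 ± 0.19 in the Cdx2 clone (79.8-fold, limma adjusted p = 1.05e-36) was called in no other clone, where its highest value was 0.40, in the Esx1 clone. Its Dox-kept signal in the Cdx2 clone was 0.68 log10, near the low end of the range, so the size of this rise is uncertain. A feature that rose by 5.46 ± 0.06 in the Klf4 clone (44.0-fold, limma adjusted p = 4.39e-59) was likewise called nowhere else, with 0.26 in the Esx1 clone as the highest other value. Over all called features, 20.1% of those of Cdx2, 16.9% of those of Esx1 and 15.9% of those of Klf4 were called in that clone alone, against 7.5% for Myc and for T and 8.8% for Pou5f1. Differences between clones were not tested feature by feature.

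In 22 of the 27 clone-by-time comparisons the Dox-kept arrays held positions 1 and 2 of a slide and the Dox-free arrays positions 3 or 4, so position and Dox state cannot be told apart there. The Pou5f1 count rose from 1277 to 2153 when the mean was taken over 48 and 72 h only, the times whose arrays share slides, a choice made after seeing the data.

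The second comparison followed the responses in time. At 24 h the number of called features ran from 172 (Pou5f1), 250 (Myc) and 314 (T) to 2351 (Esx1) and 2376 (Cdx2), with 996 for Sox2, 1401 for Klf4, 1616 for Ascl2 and 1731 for Gata3. By 48 h it had grown to 1655 (T), 1770 (Pou5f1), 1855 (Myc), 3248 (Ascl2), 3754 (Sox2), 4786 (Gata3), 5248 (Klf4), 6173 (Esx1) and 7248 (Cdx2). At 72 h it stood at 2462 for Pou5f1, 3586 for T, 4105 for Ascl2, 5814 for Sox2, 7463 for Gata3, 7820 for Klf4, 8204 for Esx1 and 8927 for Cdx2. In the Myc clone it was 1721, and whether it fell or rose from 48 h depended on the method: 1668 at 48 h and 1722 at 72 h after quantile normalization, and 1620 and 1727 without the dimmest 25% of features.

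**Figure D1:**
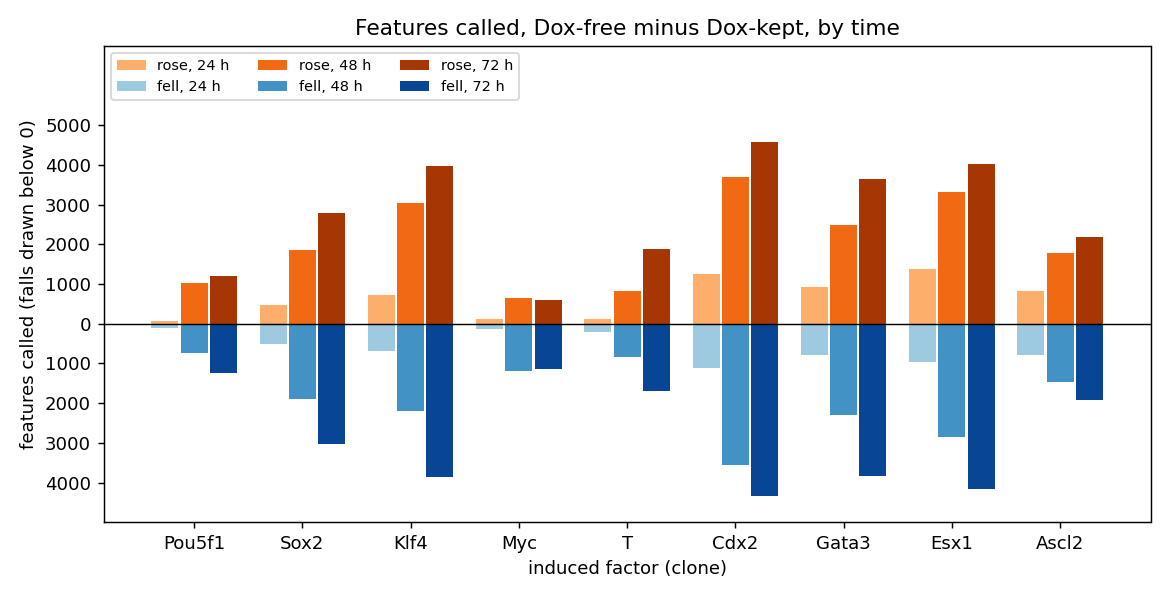
Number of features called in each clone at 24, 48 and 72 h, Dox-free minus Dox-kept; bars above 0 count rises (orange) and bars below 0 count falls (blue), darker with time. Counts grew from 24 to 72 h in every clone, from 2376 to 8927 for Cdx2 and from 172 to 2462 for Pou5f1.

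The growth was tested as the difference between the 72 h and the 24 h effect. It was called for 7561 features in the Cdx2 clone, 6357 for Esx1, 6026 for Klf4, 5658 for Gata3, 4167 for Sox2, 3005 for Ascl2, 2931 for T, 1816 for Pou5f1 and 715 for Myc (limma, adjusted p under 0.05 and a difference of at least 1.5-fold). The median change of the features that rose in the mean over times went from 0.38 at 24 h to 1.26 at 48 h and 1.84 at 72 h in the Klf4 clone, the steepest course. In the Ascl2 clone it started highest, at 0.63, and reached 1.09 and 1.26. In the Myc clone it was 0.53, 0.88 and 0.86. The falls of Pou5f1 deepened from -0.29 through -0.86 to -1.41, while its rises went from 0.33 through 0.97 to 1.06.

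**Figure D2:**
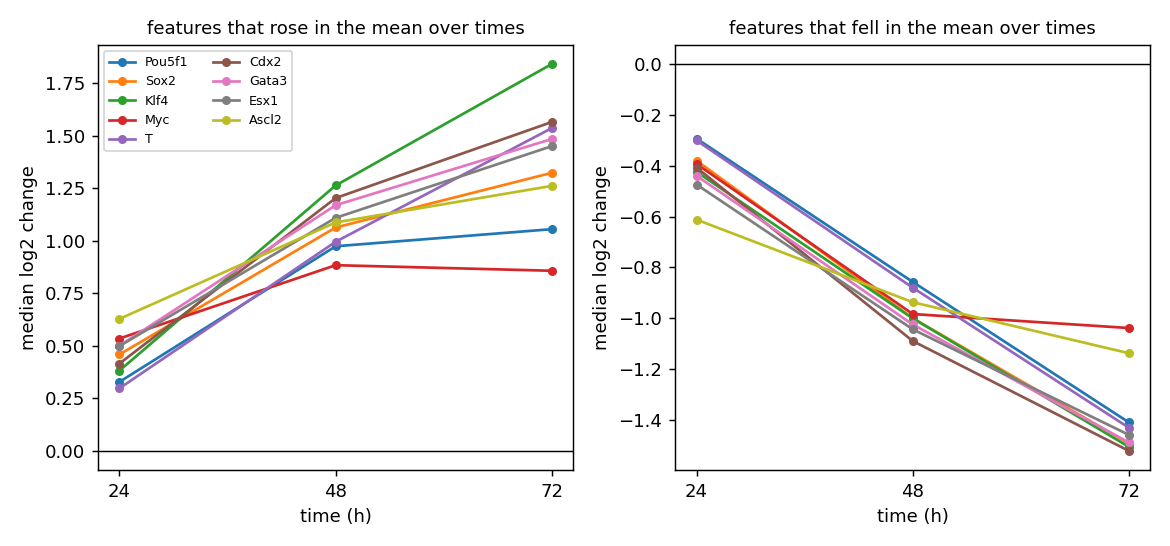
Median log2 change (y axis) at 24, 48 and 72 h (x axis) of the features that rose (left) or fell (right) in the mean over times, a line per clone. The Klf4 rises climb from 0.38 to 1.84, and the Myc lines stay level after 48 h.

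Early responders mostly persisted in the clones with the largest responses. Of the features that had risen by 24 h in the Klf4 clone, 80.7% were also called as risen at 72 h, and of those that had fallen 76.8%. The shares were 72.0% and 68.3% for Gata3, 68.4% and 60.7% for Sox2, 64.5% and 67.1% for Cdx2, and 60.1% and 72.4% for Esx1. They were lower for Ascl2, at 58.6% and 45.8%, and for Myc, at 59.7% and 37.3%. In the T clone 64.0% of the early rises were called at 72 h but only 13.8% of the early falls. In the Pou5f1 clone 31.4% and 16.7% were. Looking back from 72 h, early calls were a small part of the late response everywhere, from 1.8% of the 72 h rises in the Pou5f1 clone to 22.4% in the Ascl2 clone. Calls in opposite directions at different times were rare, with 253 features of the 11291 called at any time in the Cdx2 clone and 5 of 2693 in the Myc clone. These counts include features called at a single time, which could not be called both ways, so they understate how often early calls reversed. Of the features that had risen by 24 h in the Ascl2 clone, 34 of 835 were called as fallen at 72 h. Of those that had fallen, 33 of 781 were called as risen. In the Myc clone these were 2 of 124 and 1 of 126. The part that reversed was largest in the Cdx2 clone, where the 72 h side rests on 1 Dox-free array. Across features, the 48 h and 72 h effects correlated at 0.81 (Klf4) and 0.80 (Gata3) at the upper end. At the lower end they correlated at 0.48 (Pou5f1) and 0.49 (Myc). Features are not independent replicates.

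The 24 h comparisons of Pou5f1, Sox2 and T and the 48 h comparison of Klf4 had no slide in common between Dox-free and Dox-kept arrays, so slide and Dox state cannot be told apart there. The T count at 24 h fell from 314 to 194 without Dox-free replicate 1 and to 190 without Dox-free replicate 2, and without the dimmest 25% of features the 24 h counts were 196 for T and 107 for Pou5f1; of the Myc calls at 24 h, 49.6% were rises as deposited and 63.4% after quantile normalization.

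The third comparison asked which changes the factors had in common. A total of 12949 features were called in at least 1 clone and 12081 in none. In at least 4 of the 9 clones, 1080 features rose and 1360 fell. When each clone's calls were placed on features at random, the means were 70.6 and 55.5 (one-sided permutation p = 1e-04 each, the smallest that 10000 draws can give). Placing the calls at random within 20 classes of brightness, a test added after seeing the data, gave means of 162 and 157, with no draw of 1000 above 200. Both kinds of placement treat features as independent, so they do not allow for features that move together.

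Falls were shared more widely than rises. At least 7 clones shared 40 rises and 140 falls, and at least 8 clones shared 6 rises and 54 falls. All 9 clones shared 3 rises and 5 falls. Feature 5084 had the largest of these rises, 3.20 on the log2 scale (9.19-fold) as the mean of the clones, with single clones from 2.17 ± 0.25 (Klf4) to 4.14 ± 0.25 (Sox2). It rose by 2.24 at 24 h, 3.72 at 48 h and 3.64 at 72 h, and was called in 8 of the 9 clones at 24 h. Its signal lay between 0.46 and 1.16 log10 on the 54 Dox-kept arrays from 24 to 72 h and between 1.23 and 2.30 on the 52 Dox-free arrays, with no overlap. Feature 29749 rose by 2.38 on average, from 1.35 ± 0.31 in the T clone to 3.65 ± 0.33 in the Esx1 clone. Both started near the low end of the signal range, at 0.815 and 0.814 log10 as the mean of the Dox-kept arrays. The remaining riser gained 1.56.

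Feature 13092 fell the most among the shared features, by -2.35 on average (5.10-fold). Its falls ran from -1.03 ± 0.05 in the Myc clone and -1.15 ± 0.05 in the Pou5f1 clone to -3.48 ± 0.05 in the Sox2 clone and -3.77 ± 0.05 in the Klf4 clone. Feature 278 fell by -1.79 on average, with -3.45 ± 0.09 in the Klf4 clone and -0.60 ± 0.09 in the Myc clone. The remaining 3 averaged -1.68, -1.62 and -1.54, and 2 of these fell furthest in the Esx1 clone, by -3.59 and -4.01. The largest limma adjusted p of any of the 8 features in any clone was 0.000696. Features shared by all clones were chosen by that count, after the values were seen.

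**Figure D3:**
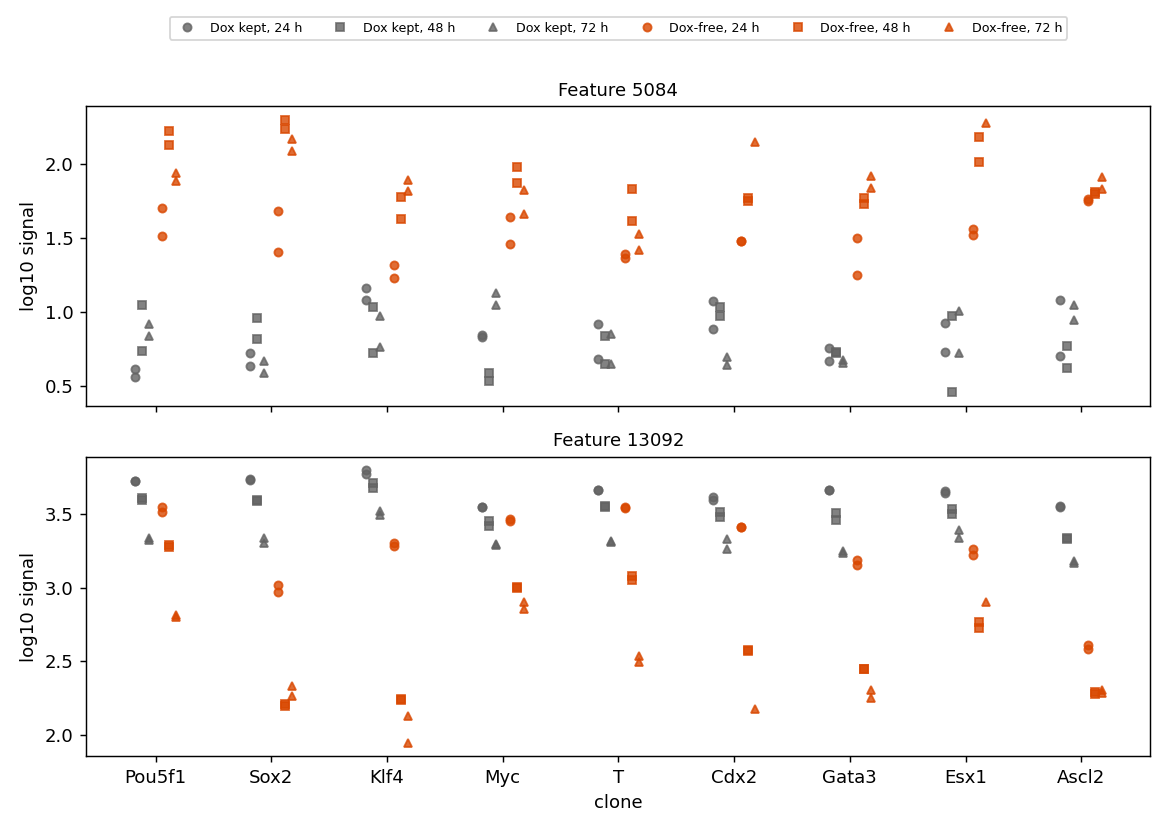
Signal on the log10 scale of feature 5084 (top) and feature 13092 (bottom) in each clone; grey points are Dox-kept and orange points Dox-free arrays, circles 24 h, squares 48 h and triangles 72 h. For feature 5084 the Dox-kept arrays end at 1.16 and the Dox-free arrays start at 1.23.

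**Figure D4:**
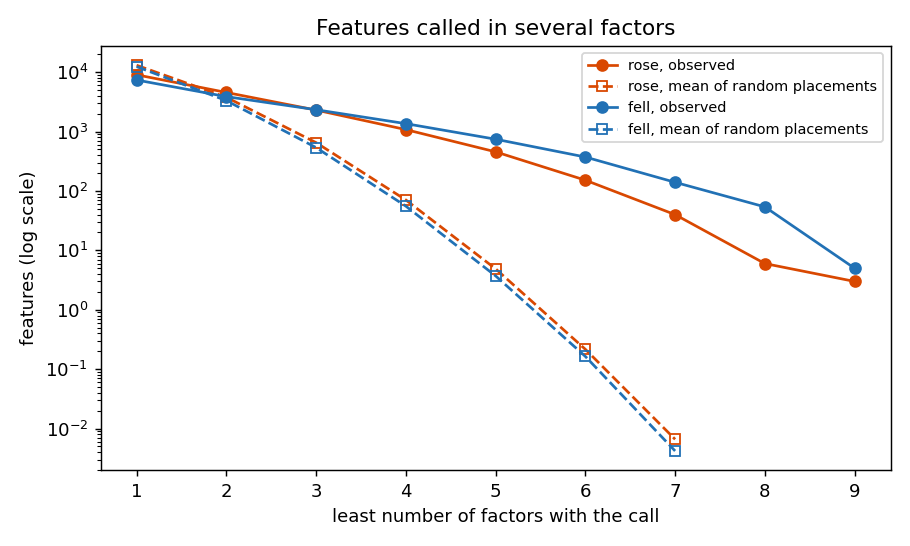
Number of features (y axis, log scale) that rose or fell in at least the number of clones on the x axis; filled circles are observed counts and open squares the mean of random placements, drawn up to 7 clones. At 7 clones or more the observed counts are 40 rises and 140 falls.

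Participation in the shared changes differed by clone. Of the features that rose in at least 6 of the other 8 clones, 84.8% also rose in the Esx1 clone, 83.0% in the Gata3 clone and 76.9% in the Cdx2 clone, 53.5% in the T clone, 8.1% in the Myc clone and 7.2% in the Pou5f1 clone. For shared falls the shares were 87.4% (Esx1), 82.5% (Cdx2), 81.7% (Gata3), 59.9% (T), 38.0% (Myc) and 13.8% (Pou5f1). Each clone had its own set of shared features, from 46 rises and 159 falls for Esx1 to 139 rises and 325 falls for Pou5f1. The shares therefore do not refer to the same set. Pou5f1 induction moved as many or more of these features against the others: 11.5% of the shared risers fell and 15.4% of the shared fallers rose. The Sox2 clone joined in 42.4% of the rises and 50.2% of the falls, and went against 15.3% and 15.1%. For the Klf4 clone these shares were 65% and 57.4% joined, and 11.7% and 10.4% against. For the Ascl2 clone they were 60.7% and 52.8% joined, and 0% and 11.6% against. These shares depend on how many features each clone called in all: of all features 10.8% fell in the Esx1 clone, 3.8% in the Myc clone, 3.6% in the T clone and 2.4% in the Pou5f1 clone. A share has an upper limit, so its ratio to such a rate is capped lower for clones with many calls. The ratio therefore does not rank the clones. Dox was removed in the Pou5f1 clone too, where 13.8% of the shared fallers fell and 15.4% rose. This argues against Dox removal alone as the cause of these falls as a set, unless Pou5f1 induction opposed it. The design has no clone without a factor. For features that changed in all clones, an effect of Dox removal by itself therefore cannot be told apart from a shared effect of the factors.

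The fourth comparison set the factors' effects side by side, over the 36 pairs. The closest were Cdx2 and Esx1, whose mean effects correlated at 0.47 across features, followed by Klf4 and Gata3 (0.46), Gata3 and Esx1 (0.43) and Cdx2 and Gata3 (0.40). Of the 3212 features called in both Cdx2 and Esx1 clones, 86.5% moved the same way, with 1361 shared rises where 431 would come from independent lists and 1417 shared falls where 332 would. Klf4 and Gata3 shared 1177 rises (314 expected) and 1081 falls (222 expected). T was nearest to Gata3 (0.36), Esx1 (0.35) and Ascl2 (0.34); T and Ascl2 shared 384 rises, 6.02 times the expected 63.8.

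Pou5f1 stood apart. Its mean correlation with the other 8 factors was 0.03, against 0.29 for Esx1, 0.28 for Cdx2 and 0.27 for Gata3. Its closest partner was Cdx2 (0.23), with 77.3% of 768 features called in both moving the same way. With T the share was 34.8% of 365, with Ascl2 38.8% of 500 and with Klf4 42.1% of 661, so most features called in both moved in opposite directions. Pou5f1 with Klf4 had the lowest correlation (-0.09). Myc was also distant, with a mean correlation of 0.09. Of the features called in both, the share that moved the same way ran from 47.6% (Pou5f1) to 73% (Esx1). Myc shared the most falls with Esx1, 521 where 103 would come from independent lists. With T it shared 249 falls, 7.28 times as many as independent lists would give. Within the clone, the 48 h and 72 h effects correlated at 0.49 for Myc and 0.48 for Pou5f1, so noise may have lowered the correlations of both factors. Sox2 and Klf4 were uncorrelated (0.03), with 874 of 1782 features called in both moving the same way.

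**Figure D5:**
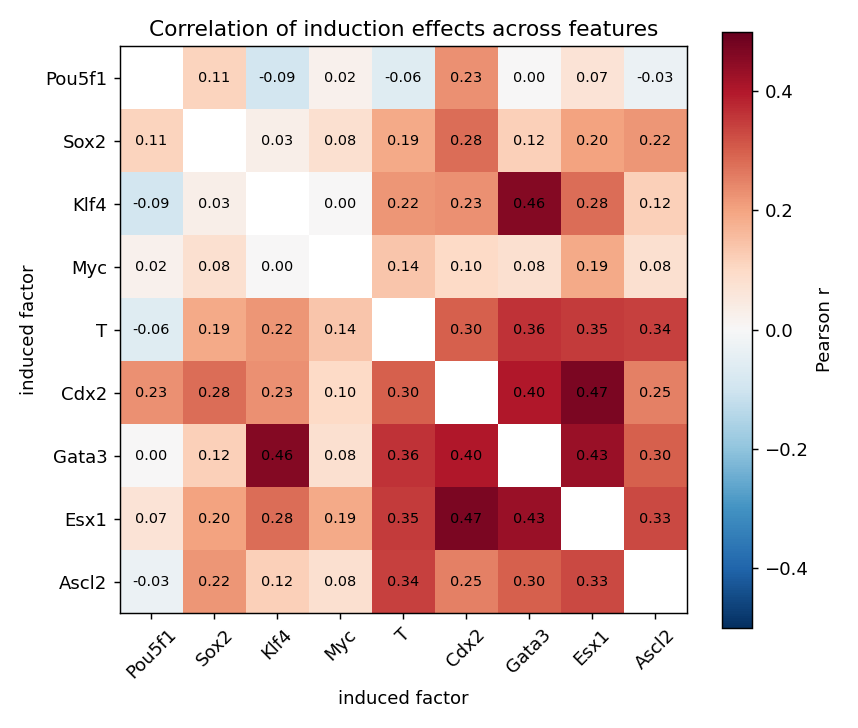
Pearson correlation across features of the mean-over-times log2 changes for each pair of induced factors; red is positive and blue negative. The highest value is 0.47 (Cdx2 and Esx1) and the lowest -0.09 (Pou5f1 and Klf4).

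Of the 36 pairs, 17 had r above 0.2 and 3 were below 0, with a median of 0.19. Shared rises and shared falls exceeded independent lists in all 36 pairs (Fisher's exact test, 2-sided, Benjamini-Hochberg adjusted over 144 tests), and so did 47 of the 72 overlaps of opposite direction, while 12 lay below. This test treats features as independent and equally likely to be called, so an excess is not by itself a likeness of effects. Pou5f1 and Klf4 shared 144 rises (78.9 expected) and had 383 opposite calls (133 expected). Correlations grew with time: the median was 0.08 at 24 h, 0.14 at 48 h and 0.24 at 72 h. At 72 h the highest was 0.47 (Klf4 and Gata3) and the lowest -0.16 (Pou5f1 and Ascl2). Effects were smaller at 24 h, and noise lowers the correlation of small effects. A clone's own 24 and 48 h effects correlated at 0.17 (Pou5f1) to 0.63 (Esx1). A growth of similarity itself is therefore not shown. No arrays are shared between clones, but the Dox-free 24 h arrays of T and Pou5f1 lie on the same slide. Their Dox-kept 24 h arrays lie on other slides, so an effect of that slide would enter both 24 h effects. This pair correlated at 0.13 at 24 h, -0.06 at 48 h and -0.07 at 72 h. Correlations across features carry no p-value here because features are not independent replicates.

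The last comparison used the 0 h arrays of 3 clones to ask what changed in culture with the vector's factor kept off. Between 0 h and the mean of 24 to 72 h with Dox kept, 1033 features rose and 1430 fell in the Pou5f1 clone, 1385 and 1546 in the Sox2 clone, and 1148 and 1222 in the T clone. The clones changed alike: 531 features rose and 608 fell in all 3, where independent lists would give 2.62 and 4.31, and the changes correlated at 0.66, 0.60 and 0.54 across features. The median change of the common features was 1.01 for rises and -0.97 for falls, and the largest were 2.71 and -2.78. The 0 h arrays lie on 3 slides that hold no other time, so slide and time cannot be told apart, and the 0 h cells were harvested without the washes and medium changes of the later times.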

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

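The additional contrast of 72 h with 48 h was chosen after the data were seen. In each of the 9 clones the effect of induction differed between 24 and 72 h by a test of the difference itself, which is why these results are listed. The difference was called for 1816 features in the Pou5f1 clone, 4167 in the Sox2 clone, 6026 in the Klf4 clone, 715 in the Myc clone, 2931 in the T clone, 7561 in the Cdx2 clone, 5658 in the Gata3 clone, 6357 in the Esx1 clone and 3005 in the Ascl2 clone. Rises and falls were near balance in most of them; in the Myc clone 211 differences were positive and 504 negative. In the Cdx2 and Esx1 clones the 72 h side rests on 1 Dox-free array, and in the Pou5f1, Sox2 and T clones the 24 h side compares arrays from different slides.

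Between 48 and 72 h, where the arrays of the Pou5f1, Sox2 and T clones share slides at each time, the difference was called for 673 (Pou5f1), 1599 (Sox2) and 1201 (T) features. It was called for 2974 in the Klf4 clone, 4403 for Cdx2, 2356 for Gata3, 3148 for Esx1, 1478 for Ascl2 and 203 for Myc. In the Pou5f1 clone 157 of these late differences were positive and 516 negative. No group has 4 or more arrays, so no array was tested for standing apart from its group.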

How the results depend on the processing

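The mean over times with a shared slide, the crossed replicate numbers, the label numbers as a block, and leaving out arrays for culture time and for shared features were chosen after seeing the data. All 51 counts stayed within 1.5 times under quantile normalization, and 49 of 51 did without the dimmest 25% of features; the counts at 24 h that moved were 107 for Pou5f1 and 196 for T, with fewer features tested. With slide as a random block (correlation within slides -0.0704) 50 of 50 counts did, and with each clone's own arrays 9 of 9. The slide block says little about slide effects, because only 3 of 55 replicate pairs lie on different slides. At 24 h, where slide and Dox state coincide, it raised the counts to 243 (Pou5f1), 428 (T) and 1143 (Sox2). Over times with a shared slide alone the Pou5f1 count was 2153, which leaves out the weak 24 h effect, and those of Sox2, T and Klf4 stayed within 1.5 times. Leaving out an array, 506 of 508 counts stayed within 1.5 times; the T count at 24 h ran from 190 to 288, with fewer arrays. Dox-free 72 h of Cdx2 and Esx1 has 1 array, which could not be left out. At least 3 factors shared 2302 rises and 2334 falls, and at least 5 shared 456 and 744, by construction. The 18 largest rises and falls kept direction and call under each alternative run on them (17 of the 18 without the dimmest 25% of features; not the mean over times with a shared slide or the crossed numbers), and no correlation of a pair moved by over 0.1. Gene-level alternatives (several probes of a gene, factor transcripts, gene lists) were not run. Signal over background was not used here, which limits the sizes of rises from dim signals.

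Arrays with the same replicate number did not deviate together throughout: over all features the correlation of their deviations ran from -0.274 to 0.0519 over 25 clone-times, with 0 above 0.1. Over bright features it ran from -0.873 to 0.424, with 10 above 0.1 and 6 under -0.1. With the replicate block, 45 of 45 counts were 0.901 to 0.998 times the unblocked ones, for example 1255 for Pou5f1 and 6293 for Cdx2 in the mean over times. For the 2 clone-times under -0.1, crossed numbers gave 2483 calls (Pou5f1, 72 h) and 279 (Myc, 24 h). The block uses the replicate numbers of the titles; the sample numbers in the other label were the same pair in both Dox states in 16 of 25 clone-times. With those as a random block (correlation -0.0422) 45 of 45 counts were 0.917 to 1 times the unblocked ones.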

Other observations

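Several tests below were chosen only after their results had been seen: those of slide position, of slide and of early timing for the features that rose in all clones, that of slide position for the shared falls, and those of shared arrays and of 0 h slides for culture time. Culture and induction moved many of the same features in opposite directions. Of the 531 features that rose in culture with Dox kept in all 3 clones, 68.5% fell on Gata3 induction, 67.4% on Klf4, 62.9% on Esx1 and 56.5% on Cdx2, while 4.90% to 10.5% rose in these clones. Of the 608 that fell in culture, 55.1% rose on Klf4 induction, 54.3% on Esx1, 45.9% on Gata3 and 39.3% on Cdx2. Myc went against culture only in part: of the features that rose in culture 24.3% fell on Myc induction and 6.97% rose, and of those that fell in culture 2.80% rose and 6.09% fell. Pou5f1 was an exception: across features its effect correlated at 0.11 and 0.14 with culture time in the Sox2 and T clones, which share no arrays with it, where the Klf4 effect correlated at -0.34 and -0.27.

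The mean culture-time change of the 3 clones correlated at -0.437 across features with the mean induction effect of the 6 clones that have no arrays in common with it, which argues against shared Dox-kept arrays as the whole cause. Within 10 classes of brightness the median correlation was -0.505, and 8 of the 10 lay under -0.1, which argues against a scaling that depends on brightness. The slides of the 0 h arrays hold 0 arrays of another time, so an effect of those slides, or of the missing washes, cannot be told apart from culture time. No biological explanation was tested.

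The wider sharing of falls was weighed against brightness and scaling. Within 4 classes of brightness, the odds that a called fall was shared by at least 7 clones were 4.08 times those of a called rise (Mantel-Haenszel 95% interval 2.86 to 5.83), so brightness alone does not account for it. After quantile normalization 140 features fell and 41 rose in at least 7 clones, a ratio of 3.41 against 3.50 as deposited, which argues against the scaling between arrays. The 325 features that fell in at least 6 of the other 8 clones had a median change of 0.10 in the Pou5f1 clone at 48 and 72 h, against -1.58 in the other clones. The 95% bootstrap interval, -0.0211 to 0.198, resamples features and does not measure spread between arrays. The Pou5f1 clone had the smallest share of the shared falls, 13.8%, so a weak change there was favoured by the choice of clone. Its arrays held the same opposed positions, which argues against position on the slide alone as the cause of these falls as a set, unless Pou5f1 induction opposed it. Dox was removed from the Pou5f1 cells too, so the same values argue against Dox removal alone as the cause of these falls as a set. That reading was made after the values were seen, and an opposing effect of Pou5f1 induction is not excluded. The values do not test why falls were shared more than rises. No biological explanation of that difference was tested.

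The 3 features that rose in all 9 clones could come from the position of the arrays, from their slides, from Dox removal or the shared vector, or from the factors. In the 24 h comparisons of Pou5f1, Sox2 and T, where Dox-free and Dox-kept arrays hold the same positions, they rose by 1.91 on average on the log2 scale (SE 0.146). The single features rose there by 2.72 (SE 0.25), 0.94 (SE 0.19) and 2.06 (SE 0.31), which argues against position as the whole cause. These values had helped to pick the features. A choice without them gave 4 features with a mean there of 1.43 (SE between features 0.604): the same 3, and another that did not rise (-0.01, SE 0.07). The rule for this verdict was rewritten after these values were seen, first to need all 4 to rise and then the 3 alone; under the rule on 4 position stayed open. In the 21 comparisons on 1 slide, from all 9 clones, the 3 rose by 2.47 on average. These comparisons are part of the means that picked the features, so a rise there was favoured by the choice. No choice without them was made. A difference between slides cannot enter a comparison on 1 slide, so it is not the source of the rises there. No comparison has the same positions on 1 slide, so effects of position in some comparisons and of slide in others are not excluded. Their change at 24 h was 0.59 of that at 72 h, with 0.614, 0.641 and 0.515 for the single features. The first yardstick was the 149 features that rose in 6 to 8 clones, with a 95th percentile of 0.589, which sets a mean against single features; 2 of the 3 lie above it. It was replaced, after that result was seen, by means of 3 drawn from those features, with a 95th percentile of 0.492. The 3 were picked for rising in every clone, so this ratio supports neither side. Their mean rise ran from 1.55 (T) to 3.14 (Esx1). Without a clone that lacks a factor, Dox removal or the vector cannot be told apart from the factors.

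The 9 counts over times were set against 100 divisions of each clone's arrays within times, drawn from 108 with the real one included. Only the real division reached the count (1 of 100). A chance division is thus an unlikely source of the counts but is not excluded. The real division also follows array position in most comparisons, so the result does not separate Dox state from position. The real counts and the highest of the others were 1277 and 1138 for Pou5f1, 3774 and 3185 for Sox2, 5257 and 4621 for Klf4, 1355 and 885 for Myc, 1883 and 1612 for T, 6373 and 5549 for Cdx2, 5075 and 4322 for Gata3, 5975 and 4992 for Esx1, and 2933 and 2197 for Ascl2. The median of the other divisions drawn was 15 to 684. Some of the other divisions kept the real Dox states at all times but 1. The highest counts of the others therefore need not come from chance alone.

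Before induction, a clone's own Dox-kept profile at 24 h, set against the other 8 clones, did not resemble its later effect: its correlation across features with the clone's own effect at 48 and 72 h ran from -0.26 (Gata3) to 0.04 (T), within the range of -0.30 to 0.24 for the effects of other factors.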
